A study of Spodoptera frugiperda with 15 samples.

How the data were processed

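The data were 15 RNA-seq libraries from whole bodies of wild-type *Spodoptera frugiperda*, 3 for each of 5 groups. RNA was extracted with TRIzol, selected for poly(A) tails and marked by strand with dUTP, per the labels' protocols, which do not say how strand was handled in counting. Reads were processed with cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2, per the submitters' processing notes, which give neither the role of each tool nor the genome build. The deposited table holds estimated counts per gene and library, written as whole numbers with no scaling per the file headers. Low values peak at multiples of about 3.83 units, so 1 read pair adds several units. The deposited FPKM values were made by the authors per the file headers, with 0.0001 as a placeholder for genes without reads.

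The table has 20784 genes, of which 12969 carry an informative description, 1458 carry none and 612 share a name with another. Descriptions are taken as deposited and rest on similarity to other species. Of the identifiers, 14385 were found in the reference name table. Of all values, 27.26% are 0. Totals per library ran from 50600821 to 77183281 units. A group at 0 in its 3 libraries was set against a floor of 3 read pairs (11.49 units) over the group, and such a fold is given as a lower bound for counting error alone.

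The groups, comparisons, tests, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. The planned test was limma-trend on log2(FPKM + 1), with edgeR instead if the table held counts. Since it held estimated counts, edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by group with a minimum count of 10) was used in R 4.3.3. One model with a coefficient for each group was fitted to the 15 libraries, and a Benjamini-Hochberg adjusted p under 0.05 counted as changed, two-sided. Limma-trend on the same tested genes, run after the data were seen, called 650, 3434, 607 and 710 genes for emamectin benzoate, tetrazolidamide, cyantraniliprole and spinetoram against control. The common dispersion was 0.3, a biological coefficient of variation of 54.8%, with 2.22 prior degrees of freedom. Exact tests of 3 against 3 libraries cannot give a p under 0.1, so none was used for single genes.

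The 34 gene lists were defined as patterns on gene descriptions, and all had at least 7 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01) on log2(FPKM + 1), adjusted over 170 tests of 34 lists in 5 comparisons, and again with an estimated correlation and with fry. The preset correlation gave 74 calls, the estimated correlation 0 and fry 38. Named genes were, for each comparison, the 8 largest rises and the 8 largest falls without overlap between groups and with an informative description, up to 2 rising and 2 falling members with the smallest p of each detoxification family, and the 2 members with the smallest p of each other called list. Ryanodine receptor and glutamate-gated chloride channel genes were named whatever their p, and no gene was described as the alpha-6 nicotinic subunit. Levels are CPM with TMM factors, as mean ± SD of 3 libraries.

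Alternatives were DESeq2 1.42.0, its size factors, no filter, a stricter filter (FPKM of 5 in 3 libraries), a fit of only the groups compared, a replicate block, limma with array weights, a fold threshold and leaving out each library in turn. Further ones, added after the data were seen, included limma-trend, counts divided by the unit of 1 read pair and a peritrophic matrix covariate. The tests were tried on data simulated for tetrazolidamide against control over 15505 genes. In steps of 1 read pair, edgeR recovered 7.5%, 52.2% and 75.8% of genes changed 2-, 4- and 8-fold with 1 false call, and DESeq2 recovered 25.4%, 71.6% and 86.4% with 74 false calls. Without such steps edgeR made 8 false calls. The simulated data used the dispersions of edgeR and the same spread in every group. No mapping was redone, since the work started from the deposited table and used neither reads nor a genome sequence.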

Results

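RNA was sequenced from whole bodies of the fall armyworm in 15 libraries, 3 from each of 5 groups. The groups were an untreated control, emamectin benzoate, tetrazolidamide, cyantraniliprole and spinetoram, and the labels give no dose, exposure time or developmental stage. The labels do not say whether the 3 libraries of a group came from separate animals or cohorts, so p-values here measure only the spread between these samples. Totals ran from 50600821 to 77183281 estimated count units per library. Of 20784 genes in the table, 15505 had enough counts to be tested. A gene described as muscle actin (LOC118279073) was the most abundant in each of the 15 libraries, with 4.9% to 9.96% of the units.

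The 3 tetrazolidamide libraries lay apart from the other 12 on the first axis of a multidimensional scaling of the 500 most divergent genes per pair, at -3.36 to -4.03 against -0.61 to 2.7. That axis held 23.4% of the variance and the next 16.9%. The control libraries were not alike, with cuticle protein scores (mean centred log2 CPM of the list) of 0.74 in control 1, -1.39 in control 2 and -1.53 in control 3. Peritrophic matrix scores in the same 3 controls were -2.26, -1.91 and 0.003. A test of any difference among the 5 groups called 3437 genes, with 5988 at an unadjusted p under 0.05. Without tetrazolidamide 1 or tetrazolidamide 3 that count was 2134 or 2242.

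**Figure D1:**
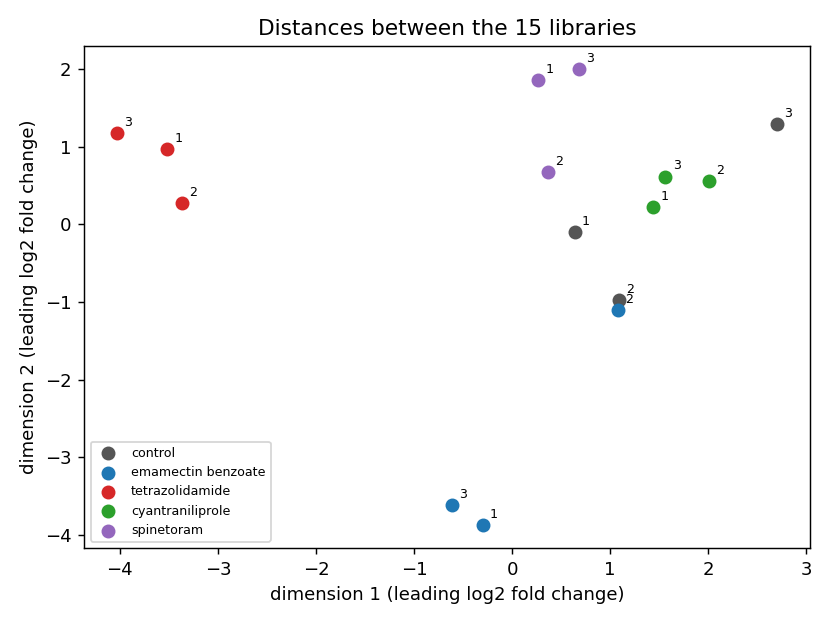
Multidimensional scaling of the 15 libraries, with leading log2 fold change on both axes and the replicate number beside each point. The 3 tetrazolidamide libraries sit between -3.36 and -4.03 on the first axis, and the other 12 between -0.61 and 2.7.

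Some digestive and detoxification genes rose after emamectin benzoate, an avermectin that acts on glutamate-gated chloride channels. A cytochrome P450 described as 6B6-like (LOC118274175), of a family known for oxidising plant toxins and insecticides, stood at 131 ± 37 CPM against 13 ± 6.2 in control (SD, n = 3), a log2 fold change of 3.33 (SE 0.47, adjusted p = 0.0083). A second 6B6-like gene (LOC118263048) reached 28.1 ± 20 CPM against 1.19 ± 0.59 (log2 fold change 4.56, adjusted p = 0.011). A chymotrypsinogen B-like gene (LOC118268184) rose to 272 ± 89 CPM from 90.8 ± 9.1, and a lipase H-A-like gene (LOC118273155) rose to 18.2 ± 7.2 from 2.18 ± 0.42, with adjusted p = 0.0083 and 0.0091. Both genes were also higher with the other 3 treatments against the same 3 controls. An acyl-CoA Delta(11) desaturase-like gene (LOC118269154) fell to 0.434 ± 0.29 CPM from 102 ± 90, a log2 fold change of -7.86 (SE 0.98, adjusted p = 0.005). In each of these 5 genes all 3 treated libraries lay beyond all 3 controls, as did 25.3% of tested genes, where chance gives 10%. The comparison addressed which transcripts, those of detoxification among them, differ from control, and 634 of 15505 genes changed, 358 higher and 276 lower. Of the 634, 631 had no overlap between the groups, so a lack of overlap adds little to a call.

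Digestive serine proteases had the lowest p of the 34 lists after emamectin benzoate, with 10 of 101 tested members higher, 1 lower and 90 not passing. Adjusted over the list alone, 43 were higher and 3 lower. Their transcripts made up 2.79 ± 0.49% of the units against 0.803 ± 0.16% in control (n = 3), and the median log2 fold change was 1.73 (camera adjusted p = 3.71e-15, and adjusted p = 0.274 with an estimated correlation). Trypsin alkaline C-like (LOC118277912) was among the risen, at 118 ± 17 CPM against 36 ± 7.8 (adjusted p = 0.009). Other digestive enzymes had 14 of 116 higher and 6 lower (adjusted over the list alone 22 and 9; camera adjusted p = 0.00018, and adjusted p = 0.555 with an estimated correlation). The CYP6 and CYP9 list had 6 of 50 higher and 0 lower by edgeR at a median of 0.83 (adjusted over the list alone 11 and 0; camera adjusted p = 6.04e-05, and adjusted p = 0.555 with an estimated correlation). All P450s together had 9 of 127 higher and 1 lower (adjusted over the list alone 14 and 2; camera adjusted p = 0.00135, and adjusted p = 0.568 with an estimated correlation). CYP306A1 (LOC118266714), a hydroxylase of ecdysteroid synthesis, rose to 56.7 ± 0.12 CPM from 20.3 ± 3.3 (adjusted p = 0.0069). Carboxyl/cholinesterases had 8 of 73 higher and 0 lower (adjusted over the list alone 21 and 2; camera adjusted p = 8.93e-06, and adjusted p = 0.428 with an estimated correlation). UDP-glycosyltransferases had 3 of 40 higher and 1 lower (adjusted over the list alone 7 and 3; camera adjusted p = 0.0027, and adjusted p = 0.568 with an estimated correlation).

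Antimicrobial peptides and lysozymes were higher as a list after emamectin benzoate at a median of 1.05, with 1 of 33 members passing (adjusted over the list alone 1; camera adjusted p = 0.000141, and adjusted p = 0.587 with an estimated correlation). The passing member was lysozyme-like protein 1 (LOC118279309), at 320 ± 65 CPM against 154 ± 19, with adjusted p = 0.034. Its adjusted p was 0.063, 0.087 and 0.059 without control 1, 2 and 3, and 0.11 and 0.13 without emamectin benzoate 1 and 3. V-type proton ATPase subunits had 1 of 22 higher (adjusted over the list alone 9; camera adjusted p = 0.000602, and adjusted p = 0.588 with an estimated correlation). Proteasome subunits were lower at a median of -0.24, with 0 of 42 members passing by edgeR or over the list alone (camera adjusted p = 6.02e-06, and adjusted p = 0.588 with an estimated correlation). Ecdysteroid and juvenile hormone genes had 0 of 43 higher and 4 lower (adjusted over the list alone 1 and 9; camera adjusted p = 0.0114, and adjusted p = 0.568 with an estimated correlation). This call ended without control 3 (adjusted p = 0.06). Hormone receptor 4 (LOC118262489) and the receptor HR3 (LOC118279845), both of the ecdysone response, fell to 1.3 ± 1.3 and 2.62 ± 1.9 CPM from 34.1 ± 18 and 81 ± 73, and without emamectin benzoate 3 their adjusted p were 0.052 and 0.054. Of the 4 glutamate-gated chloride channel genes, LOC118268071 had 3.5 ± 0.84 CPM against 2.63 ± 0.88 and LOC118268221 had 0.683 ± 0.43 against 0.341 ± 0.3. LOC118277861 had 4.9 ± 2.5 against 6.44 ± 2.9 and LOC118277865 had 6.15 ± 1.9 against 6.1 ± 0.91, with adjusted p from 0.62 to 1. Peritrophic matrix and midgut markers, 0 of 12 passing, had a median of 1.11 in the same libraries (camera adjusted p = 0.0204, and adjusted p = 0.588 with an estimated correlation).

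The calls of some smaller lists after emamectin benzoate ended without 1 library. CYP4 family P450s were higher (members by edgeR 2 higher and 0 lower of 58, adjusted over the list alone 3 and 0; camera adjusted p = 0.0379, and adjusted p = 0.594 with an estimated correlation), with an adjusted p of up to 0.41 without control 1 or emamectin benzoate 3. Glutathione S-transferases were higher (members by edgeR 1 higher and 0 lower of 21, adjusted over the list alone 4 and 0; camera adjusted p = 0.0151, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of 0.058 without control 3. Ryanodine receptor and calcium handling genes were lower (members by edgeR 0 higher and 0 lower of 17, adjusted over the list alone 0 and 1; camera adjusted p = 0.0376, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of up to 0.17 without control 1, control 2, emamectin benzoate 1 or emamectin benzoate 2. The peritrophic matrix list lost its call without control 1, control 2 or emamectin benzoate 1 (adjusted p up to 0.14). The gene count was 272 without control 1, and 150, 402 and 45 without emamectin benzoate 1, 2 and 3. It was 0 in an edgeR fit of only the 6 libraries (2574 genes at an unadjusted p under 0.05, and 1503 past the threshold by DESeq2), and 1783 by DESeq2 on all 15. The balance of directions turned in some fits, with 162 higher and 297 lower without control 2 and 848 higher and 935 lower by DESeq2.

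Many cuticle genes rose and many proteasome and glycolysis genes fell after tetrazolidamide, a compound the labels describe by name alone. Cuticle protein 64-like (LOC118276094) stood at 835 ± 304 CPM against 8.92 ± 2.6 in control (SD, n = 3), a log2 fold change of 6.55 (SE 0.67, adjusted p = 0.00012). Endocuticle glycoprotein SgAbd-5-like (LOC118282288) rose to 1181 ± 168 CPM from 55.1 ± 24 (log2 fold change 4.42, SE 0.46, adjusted p = 0.00012). A P450 described as 4C1-like (LOC118275193) rose to 48 ± 16 CPM from 2.61 ± 0.58, while one described as 6k1-like (LOC118263012) fell to 2.39 ± 1.7 from 51.1 ± 7.4, with adjusted p = 0.0001 and 0.00011. The 4C1-like gene was also higher with the other 3 treatments against the same 3 controls. The question was again which transcripts differ from control, and 3452 of 15505 genes changed, 1688 higher and 1764 lower. In each of these 4 genes all 3 treated libraries lay beyond all 3 controls, as did 36.6% of tested genes, where chance gives 10%, and 3311 of the 3452 changed genes.

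Of 170 tested cuticle proteins, which build the exoskeleton with chitin, 76 rose with tetrazolidamide, 7 fell and 87 did not pass (adjusted over the list alone 92 higher and 10 lower). Their share of the units was 5.66 ± 0.5% against 3.44 ± 0.43% in control (n = 3), and the median log2 fold change was 2.79 (camera adjusted p = 1.19e-22, and adjusted p = 0.383 with an estimated correlation). The cuticle score was 1.98, 1.66 and 2.25 in the tetrazolidamide libraries, above control 1 at 0.74. Peritrophic matrix and midgut markers had 5 of 12 higher and 0 lower by edgeR (adjusted over the list alone 6 and 0; camera adjusted p = 0.00122, and adjusted p = 0.555 with an estimated correlation). Among them, peritrophin-44-like (LOC118279986) was at 20.3 ± 9.5 CPM against 0 in the 3 controls, at least 319-fold higher. V-type proton ATPase subunits, of the pump that acidifies organelles and energises the insect midgut, had 16 of 22 higher and 0 lower (adjusted over the list alone 16 and 0; camera adjusted p = 4.79e-06, and adjusted p = 0.555 with an estimated correlation). Subunit e 2-like (LOC118279038) reached 285 ± 15 CPM against 140 ± 23 and subunit H (LOC118271665) 398 ± 19 against 200 ± 31. Chemosensory proteins had 8 of 43 higher and 1 lower (adjusted over the list alone 9 and 2; camera adjusted p = 0.0118, and adjusted p = 0.555 with an estimated correlation). Odorant-binding protein 28a-like (LOC118267783) rose to 41 ± 18 CPM from 9.38 ± 3.2.

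Proteasome subunits, which degrade tagged proteins, were lower after tetrazolidamide, with 29 of 42 fallen and 0 risen by edgeR (adjusted over the list alone 35 and 0). The median was -0.66 (camera adjusted p = 2.47e-13, and adjusted p = 0.555 with an estimated correlation). Subunit beta type-5 (LOC118277502) was at 48 ± 0.79 CPM against 79.8 ± 2.8, and regulatory subunit 13-like (LOC118280467) at 27.9 ± 3.1 against 61.3 ± 6.2. Glycolysis had 11 of 15 members lower and 0 higher (adjusted over the list alone 12 and 1; camera adjusted p = 4.79e-06, and adjusted p = 0.555 with an estimated correlation). Its strongest members were 2 aldolase genes, LOC118274664 at 7.02 ± 2 CPM against 298 ± 97 and LOC118275099 at 0.091 ± 0.11 against 37.1 ± 9.7. Both lay in a row of 9 neighbouring tested genes that were all lower by more than 3 on the log2 scale. Other aldolase genes had 554.3 CPM against 761.5 (LOC118274716, adjusted p = 0.111) and 64.4 against 67.56 (LOC118275119, adjusted p = 0.946), both named after their values were seen. DNA replication and mitosis had 7 of 33 lower and 0 higher (adjusted over the list alone 15 and 0; camera adjusted p = 0.00012, and adjusted p = 0.588 with an estimated correlation). PCNA (LOC118261842), the sliding clamp of DNA polymerase, was at 10.7 ± 1.6 CPM against 23.4 ± 8.3. In a fit of only these 6 libraries the PCNA adjusted p was 0.076.

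Detoxification genes went both ways after tetrazolidamide. ABC transporters had 14 of 55 higher and 4 lower (adjusted over the list alone 16 and 5; camera adjusted p = 0.00976, and adjusted p = 0.587 with an estimated correlation). Their median was 0.35 and their mean -0.03. One gene described as ABC transporter G family member 20 (LOC118270342) rose to 57.9 ± 3.2 CPM from 9.04 ± 0.94 and another (LOC118270337) was at 0 in the 3 treated libraries against 1.23 ± 0.97, at least 19.2-fold lower. Carboxyl/cholinesterases had 16 of 73 higher and 4 lower (adjusted over the list alone 17 and 5; camera adjusted p = 0.0121, and adjusted p = 0.555 with an estimated correlation). Esterase FE4-like (LOC118273652) rose to 4.13 ± 0.78 CPM from 0.768 ± 0.27. The CYP6 and CYP9 list was not called (3 of 50 higher and 10 lower, adjusted over the list alone 3 and 11; camera adjusted p = 0.974), nor were all P450s (9 of 127 higher and 19 lower), UDP-glycosyltransferases (6 of 40 higher and 4 lower) or glutathione S-transferases (4 of 21 higher and 3 lower). A UDP-glucuronosyltransferase 2C1 gene (LOC118267687) fell to 3.18 ± 0.91 CPM from 24.6 ± 11. Of lipid metabolism genes 21 of 118 were higher and 12 lower (adjusted over the list alone 22 and 12; camera adjusted p = 0.00565, and adjusted p = 0.602 with an estimated correlation). This call ended without control 1 (adjusted p = 0.093). A lipid storage droplet protein (LOC118269580) rose to 132 ± 8.9 CPM from 33.5 ± 14 and the desaturase LOC118269154 fell to 0.891 ± 0.38 from 102 ± 90. CYP4 family P450s had a median of 0.51 and a mean of -0.06. They were called higher with 5 of 58 members higher and 4 lower by edgeR (adjusted over the list alone 4 and 3; camera adjusted p = 0.0482, and adjusted p = 0.596 with an estimated correlation). The adjusted p reached 0.31 without control 1, tetrazolidamide 1 or tetrazolidamide 3. The gene count was 1583 in an edgeR fit of only the 6 libraries and 2276 with a stricter filter.

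A set of genes had no counts at all in the 3 tetrazolidamide libraries. Of the tested genes, 36 were at 0 there and above 0 in each of the other 12 libraries, against 2, 1, 1 and 2 such genes for control, emamectin benzoate, cyantraniliprole and spinetoram. One described as small nuclear ribonucleoprotein Sm D2 (LOC118270397), a splicing factor, had 9.32 ± 1.4 CPM in control and was at least 145-fold lower, in a row of 7 neighbouring tested genes lower by more than 3 on the log2 scale. A further gene with that description (LOC118270441), named after its values were seen, had 19.9 ± 1.8 CPM against 17.2 ± 3.4 in control (edgeR adjusted p = 0.4). Another stretch was picked as the window of 500 kb with the most of the 36 genes, 9 of them. In it 18 of 20 neighbouring tested genes fell, and the 9 among these were low by that choice. Tubulin beta chain-like (LOC118280826), not 1 of the 9 and named after its values were seen, fell from 18.3 to 0.262 CPM. A glutamate-gated chloride channel gene (LOC118268221) was at 0 against 0.341 ± 0.3 CPM, at least 5.6-fold lower (adjusted p = 0.013). There 0 of the 3 treated libraries lay below all 3 controls, and the adjusted p was 0.17 in a fit of only the 6 libraries. Another (LOC118268071) rose to 8.71 ± 1.4 CPM from 2.63 ± 0.88, and LOC118277861 and LOC118277865 had 8.06 ± 1.5 and 5.32 ± 2.4 CPM against 6.44 ± 2.9 and 6.1 ± 0.91. The ryanodine receptor gene LOC118277034 stood at 248 ± 75 CPM against 135 ± 43 (log2 fold change 0.88, adjusted p = 0.048), and its adjusted p was 0.067, 0.15, 0.074 and 0.19 without control 1, control 3, tetrazolidamide 1 and tetrazolidamide 3. The other ryanodine receptor gene, LOC118276673, had 328 ± 56 CPM against 388 ± 103 (adjusted p = 0.54).

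A pair of lipase genes, a chymotrypsinogen gene and a peritrophin gene were among those that rose after cyantraniliprole, a diamide that activates the ryanodine receptor. The lipase H-A-like genes LOC118273155 and LOC118273165 stood at 28.4 ± 8.1 and 59.1 ± 25 CPM against 2.18 ± 0.42 and 4.72 ± 0.85 in control (SD, n = 3), log2 fold changes of 3.70 and 3.65 (SE 0.48 and adjusted p = 0.0042 for each). Chymotrypsinogen B-like (LOC118268184) rose to 325 ± 61 CPM from 90.8 ± 9.1 and a peritrophin-like gene (LOC118274190), of the matrix that lines the midgut, to 424 ± 108 from 39.4 ± 24. The lipase and chymotrypsinogen genes were also higher with the other 3 treatments against the same 3 controls. A UDP-glucuronosyltransferase 2B19-like gene (LOC118279189), of a family that conjugates sugars to toxins, rose to 62.4 ± 25 CPM from 6.23 ± 4.5 (log2 fold change 3.32, SE 0.57, adjusted p = 0.016). In each of these 5 genes all 3 treated libraries lay above all 3 controls. Of tested genes 23.4% had no overlap between the groups, where chance gives 10%. Every changed gene had none, so this adds little to a call. Against the same question, 406 of 15505 genes changed, 309 higher and 97 lower.

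Digestive serine proteases had 4 of 101 members higher after cyantraniliprole and 0 lower by edgeR (adjusted over the list alone 10 and 1), with a share of 1.49 ± 0.65% of the units against 0.803 ± 0.16% (camera adjusted p = 1.33e-05, and adjusted p = 0.555 with an estimated correlation). Other digestive enzymes had 8 of 116 higher and 0 lower (adjusted over the list alone 18 and 0; camera adjusted p = 1.68e-05, and adjusted p = 0.555 with an estimated correlation). The CYP6 and CYP9 list had 2 of 50 higher and 0 lower at a median of 0.89 (adjusted over the list alone 11 and 0; camera adjusted p = 1.33e-05, and adjusted p = 0.555 with an estimated correlation). P450s had 6 of 127 higher (adjusted over the list alone 9; camera adjusted p = 0.000298, and adjusted p = 0.555 with an estimated correlation). UDP-glycosyltransferases had 5 of 40 higher (adjusted over the list alone 6; camera adjusted p = 0.000164, and adjusted p = 0.555 with an estimated correlation). Carboxyl/cholinesterases had 2 of 73 higher and 0 lower (adjusted over the list alone 8 higher and 1 lower; camera adjusted p = 0.000287, and adjusted p = 0.555 with an estimated correlation). Antimicrobial peptides and lysozymes had a median of 1.26 with 0 of 33 passing by edgeR or over the list alone (camera adjusted p = 5.57e-07, and adjusted p = 0.555 with an estimated correlation). The lysozyme-like gene LOC118265131 was at 564 ± 98 CPM against 146 ± 67 (adjusted p = 0.054). Lipid metabolism had 3 of 118 higher and 1 lower (adjusted over the list alone 11 and 1; camera adjusted p = 6.84e-05, and adjusted p = 0.572 with an estimated correlation). V-type proton ATPase had 0 of 22 passing by edgeR (adjusted over the list alone 6; camera adjusted p = 0.000871, and adjusted p = 0.588 with an estimated correlation).

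Oxidative phosphorylation genes were lower as a list after cyantraniliprole at a median of -0.4, with 1 of 78 fallen (adjusted over the list alone 1; camera adjusted p = 2.41e-11, and adjusted p = 0.573 with an estimated correlation). Their share of the units was 1.401% to 1.508% with cyantraniliprole and 1.37% to 2.067% in control, so the lowest control lay below every treated library. Muscle structural proteins held 15.9 ± 1.7% against 20.5 ± 4.8% in the same libraries. The fallen member was NADH dehydrogenase flavoprotein 2 (LOC118272875), of respiratory complex I, at 17 ± 0.21 CPM against 54.4 ± 21 (adjusted p = 0.011). The ubiquinone biosynthesis gene COQ4 (LOC118262767) also fell, to 0.593 ± 0.37 CPM from 4.96 ± 1.4 (adjusted p = 0.0084). Proteasome subunits had 2 of 42 lower (adjusted over the list alone 13; camera adjusted p = 1.05e-06, and adjusted p = 0.587 with an estimated correlation). DNA replication and mitosis had 3 of 33 lower (adjusted over the list alone 7; camera adjusted p = 1.46e-05, and adjusted p = 0.573 with an estimated correlation). Outside the lists, a gene described as a cytokine receptor (LOC118281769) rose to 6.5 ± 1.2 CPM from 0.367 ± 0.16. Among the hemocyte markers, integrin beta-nu (LOC118272167), which binds apoptotic cells in hemocytes, rose to 13.8 ± 1.4 from 6.69 ± 0.64. The ryanodine receptor genes LOC118276673 and LOC118277034 had 314 ± 90 and 100 ± 4.6 CPM against 388 ± 103 and 135 ± 43, log2 fold changes of -0.31 (95% interval -0.86 to 0.25) and -0.42 (-1.05 to 0.20), neither past the threshold. The glutamate-gated chloride channel genes had adjusted p of 0.27 (LOC118268071), 0.71 (LOC118268221), 0.57 (LOC118277861) and 0.64 (LOC118277865).

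The calls of further lists after cyantraniliprole ended without 1 library. CYP4 family P450s were higher (members by edgeR 2 higher and 0 lower of 58, adjusted over the list alone 2 and 0; camera adjusted p = 0.0432, and adjusted p = 0.594 with an estimated correlation), with an adjusted p of up to 0.36 without control 1, control 3, cyantraniliprole 1 or cyantraniliprole 2. ABC transporters were higher (members by edgeR 1 higher and 0 lower of 55, adjusted over the list alone 1 and 0; camera adjusted p = 0.0194, and adjusted p = 0.588 with an estimated correlation), with an adjusted p of up to 0.076 without control 1 or control 2. Xenobiotic response regulators were higher (members by edgeR 2 higher and 0 lower of 7, adjusted over the list alone 3 and 0; camera adjusted p = 0.0176, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of 0.057 without cyantraniliprole 1. Peritrophic matrix and midgut markers were higher (members by edgeR 1 higher and 0 lower of 12, adjusted over the list alone 1 and 0; camera adjusted p = 0.0208, and adjusted p = 0.588 with an estimated correlation), with an adjusted p of up to 0.14 without control 1 or cyantraniliprole 3. Hemocyte markers were higher (members by edgeR 1 higher and 0 lower of 22, adjusted over the list alone 4 and 0; camera adjusted p = 0.0329, and adjusted p = 0.602 with an estimated correlation), with an adjusted p of up to 0.2 without control 1, control 2 or cyantraniliprole 3. Muscle structural proteins were lower (members by edgeR 1 higher and 0 lower of 39, adjusted over the list alone 1 and 0; camera adjusted p = 0.0027, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of 0.094 without control 2. Ryanodine receptor and calcium handling genes were lower (members by edgeR 0 higher and 0 lower of 17, adjusted over the list alone 0 and 0; camera adjusted p = 0.0151, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of up to 0.075 without control 1 or control 2. Glycolysis genes were lower (members by edgeR 1 higher and 1 lower of 15, adjusted over the list alone 1 and 4; camera adjusted p = 0.00311, and adjusted p = 0.587 with an estimated correlation), with an adjusted p of 0.15 without control 2. The gene count was 208, 78 and 1214 without control 1, 2 and 3, and 152, 205 and 100 without cyantraniliprole 1, 2 and 3. It was 0 in an edgeR fit of only the 6 libraries (2343 genes at an unadjusted p under 0.05, and 1005 past the threshold by DESeq2), and 1532 by DESeq2 on all 15. The excess of rises was smaller without control 3 (696 higher and 518 lower) and by DESeq2 (920 and 612).

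Some lipase, protease and cuticle genes rose after spinetoram, a spinosyn that acts on nicotinic acetylcholine receptors. The lipase H-A-like genes LOC118273155 and LOC118273165 stood at 91.9 ± 32 and 165 ± 51 CPM against 2.18 ± 0.42 and 4.72 ± 0.85 in control (SD, n = 3), log2 fold changes of 5.40 and 5.13 (SE 0.51 and 0.52, adjusted p = 0.0017 for each). Endocuticle glycoprotein SgAbd-5-like (LOC118282288) rose to 448 ± 228 CPM from 55.1 ± 24, and cuticle protein 19-like (LOC118262049) to 5.95 ± 1 from 1.81 ± 0.49, with adjusted p = 0.0084 and 0.01. The lipase genes and cuticle protein 19-like were also higher with the other 3 treatments against the same 3 controls. A gene described as dentin sialophosphoprotein-like (LOC118280206) fell to 0.613 ± 0.043 CPM from 3.7 ± 0.9 (log2 fold change -2.59, SE 0.33, adjusted p = 0.0049). In each of these 5 genes all 3 treated libraries lay beyond all 3 controls, as did 21.6% of tested genes, where chance gives 10%. In all, 622 of 15505 genes changed, 448 higher and 174 lower. Of the 622, 618 had no overlap between the groups.

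Digestive serine proteases had 11 of 101 members higher after spinetoram and 0 lower by edgeR (adjusted over the list alone 32 and 1), at 2.32 ± 0.49% of the units against 0.803 ± 0.16% (camera adjusted p = 4.44e-15, and adjusted p = 0.274 with an estimated correlation). Other digestive enzymes had 14 of 116 higher and 0 lower (adjusted over the list alone 24 and 0; camera adjusted p = 7.3e-10, and adjusted p = 0.463 with an estimated correlation). Peritrophic matrix markers had 1 of 12 higher (adjusted over the list alone 1; camera adjusted p = 0.00406, and adjusted p = 0.572 with an estimated correlation). Cuticle proteins had 17 of 170 higher and 0 lower at a median of 1.17 (adjusted over the list alone 34 and 0; camera adjusted p = 5.89e-13, and adjusted p = 0.555 with an estimated correlation). Their scores were 1.42, -0.075 and 1.15 in the 3 libraries and 0.74 in control 1. Carboxyl/cholinesterases had 9 of 73 higher and 1 lower (adjusted over the list alone 21 and 2; camera adjusted p = 3.12e-08, and adjusted p = 0.274 with an estimated correlation). The CYP6 and CYP9 list had 4 of 50 higher and 0 lower at a median of 0.45 (adjusted over the list alone 5 and 0; camera adjusted p = 0.000733, and adjusted p = 0.568 with an estimated correlation). CYP321B1 (LOC118262947) was at 3.04 ± 0.44 CPM against 0.442 ± 0.25 and an adjusted p of 0.051 without control 2. Antimicrobial peptides and lysozymes had a median of 1.56 with 0 of 33 passing by edgeR (adjusted over the list alone 4; camera adjusted p = 1.29e-06, and adjusted p = 0.555 with an estimated correlation).

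Lipid metabolism had 7 of 118 members higher after spinetoram and 0 lower by edgeR (adjusted over the list alone 8 and 0; camera adjusted p = 4.43e-07, and adjusted p = 0.555 with an estimated correlation). V-type proton ATPase had 5 of 22 higher, a median of 0.65 and a mean of -0.06 (adjusted over the list alone 15 higher and 1 lower; camera adjusted p = 1.28e-05, and adjusted p = 0.568 with an estimated correlation). DNA replication had 2 of 33 lower at a median of -0.77 (adjusted over the list alone 9; camera adjusted p = 5.24e-07, and adjusted p = 0.555 with an estimated correlation). Proteasome subunits were lower as a list at a median of -0.17 (camera adjusted p = 1e-04, and adjusted p = 0.602 with an estimated correlation), and over the list alone 1 was higher and 2 lower. The 1 member past the threshold by edgeR, subunit alpha type-3 (LOC118267530), rose to 27.4 ± 8.8 CPM from 6.34 ± 4.9. Its adjusted p was 0.039, and 0.089, 0.066, 0.12 and 0.089 without control 1, control 2, spinetoram 1 and spinetoram 2. The nicotinic acetylcholine receptor subunits had 0 of 15 members passing by edgeR (adjusted over the list alone 0; median 0.11; camera adjusted p = 0.406). The ryanodine receptor genes LOC118276673 and LOC118277034 had adjusted p of 0.26 and 0.63, and the chloride channel genes LOC118268071, LOC118268221, LOC118277861 and LOC118277865 had 0.43, 0.71, 0.66 and 0.48.

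The calls of further lists after spinetoram ended without 1 library. All P450s together were higher (members by edgeR 7 higher and 0 lower of 127, adjusted over the list alone 7 and 0; camera adjusted p = 0.00523, and adjusted p = 0.587 with an estimated correlation), with an adjusted p of 0.08 without control 1. Glutathione S-transferases were higher (members by edgeR 1 higher and 0 lower of 21, adjusted over the list alone 2 and 0; camera adjusted p = 0.0487, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of up to 0.15 without control 2, control 3, spinetoram 2 or spinetoram 3. ABC transporters were higher (members by edgeR 2 higher and 0 lower of 55, adjusted over the list alone 7 and 1; camera adjusted p = 0.0487, and adjusted p = 0.602 with an estimated correlation), with an adjusted p of up to 0.17 without control 1, control 2, spinetoram 1 or spinetoram 2. Muscle structural proteins were lower (members by edgeR 1 higher and 1 lower of 39, adjusted over the list alone 1 and 4; camera adjusted p = 0.00143, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of 0.06 without control 2. Oxidative phosphorylation genes were lower (members by edgeR 0 higher and 0 lower of 78, adjusted over the list alone 0 and 0; camera adjusted p = 0.000183, and adjusted p = 0.705 with an estimated correlation), with an adjusted p of up to 0.19 without control 1 or control 2. Glycolysis genes were lower (members by edgeR 0 higher and 0 lower of 15, adjusted over the list alone 0 and 0; camera adjusted p = 0.014, and adjusted p = 0.596 with an estimated correlation), with an adjusted p of up to 0.25 without control 2 or spinetoram 3. Cytosolic ribosomal proteins were higher (members by edgeR 0 higher and 0 lower of 86, adjusted over the list alone 0 and 0; camera adjusted p = 0.0463, and adjusted p = 0.856 with an estimated correlation), with an adjusted p of up to 0.51 without control 1, control 2, control 3, spinetoram 1 or spinetoram 2. The gene count was 35 without control 2, 1118 without control 3, and 222 without spinetoram 1 or spinetoram 2. It was 2 in an edgeR fit of only the 6 libraries (998 by DESeq2), and 1880 by DESeq2 on all 15. The split between directions was nearer even by limma-trend (384 higher and 326 lower), by limma with array weights (546 and 413), by DESeq2 (1105 and 775) and without control 3 (665 and 453).

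**Figure D2:**
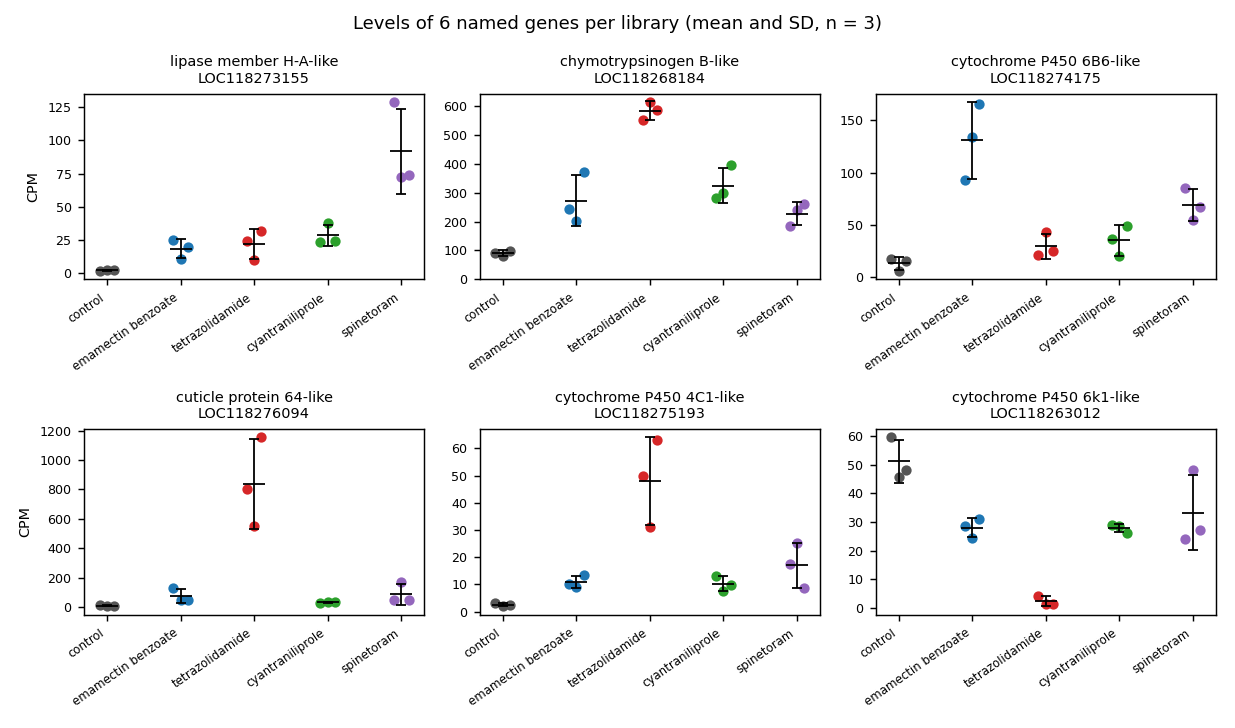
CPM per library of 6 genes, with bars for the mean and SD (n = 3) and 1 panel per gene. The lipase H-A-like gene averages 91.9 CPM in spinetoram against 2.18 in control, and cuticle protein 64-like 835 in tetrazolidamide against 8.92.

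Some immune and CYP6 genes were higher, and some cuticle genes lower, with cyantraniliprole than with tetrazolidamide. Peptidoglycan-recognition protein LB-like (LOC118274476), which degrades bacterial cell wall fragments, stood at 87.4 ± 10 CPM with cyantraniliprole against 9.42 ± 1 with tetrazolidamide (SD, n = 3), a log2 difference of 3.21 (SE 0.44, adjusted p = 0.0016). Spaetzle 4 (LOC118272073), of the Toll ligand family, was at 68.1 ± 15 CPM against 2.19 ± 0.58 and an attacin-like gene (LOC118279268), an antibacterial peptide, at 28.4 ± 8.2 against 0.881 ± 0.25, with adjusted p = 0.003 and 0.0087. CYP6B68 (LOC118273914) was at 105 ± 41 CPM against 13.7 ± 0.45 (log2 difference 2.94, SE 0.32, adjusted p = 0.00037). Pupal cuticle protein C1B-like (LOC118272659) was at 2.54 ± 0.56 CPM against 452 ± 36 (log2 difference -7.48, SE 0.82, adjusted p = 0.00045). In each of these 5 genes the 3 libraries of one group lay beyond all 3 of the other, as in 35.1% of tested genes, where chance gives 10%. This direct comparison of 2 treatments, whose doses and times the labels do not give, found 1724 of 15505 genes different, 1005 higher with cyantraniliprole and 719 lower.

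Of 33 antimicrobial peptides and lysozymes, 11 were higher with cyantraniliprole than with tetrazolidamide and 1 lower (adjusted over the list alone 18 and 1; median 2.58; camera adjusted p = 9.44e-05, and adjusted p = 0.582 with an estimated correlation). Immune recognition and melanization had 9 of 32 higher and 0 lower by edgeR (adjusted over the list alone 11 and 0; camera adjusted p = 0.00572, and adjusted p = 0.555 with an estimated correlation). The CYP6 and CYP9 list had 12 of 50 higher and 0 lower (adjusted over the list alone 14 and 0; median 0.62; camera adjusted p = 0.000321, and adjusted p = 0.555 with an estimated correlation). The 6k1-like gene (LOC118263012) was at 27.9 ± 1.5 CPM against 2.39 ± 1.7. Cuticle proteins had 63 of 170 lower and 3 higher (adjusted over the list alone 88 and 8; median -2.29; camera adjusted p = 1.87e-27, and adjusted p = 0.274 with an estimated correlation). Proteasome subunits had 7 of 42 higher (adjusted over the list alone 15; camera adjusted p = 3.12e-08, and adjusted p = 0.572 with an estimated correlation). Glycolysis had 3 of 15 higher (adjusted over the list alone 3; camera adjusted p = 1e-04, and adjusted p = 0.555 with an estimated correlation). These included both aldolase genes of the stretch that was low in tetrazolidamide. Oxidative phosphorylation was lower at a median of -0.43, with 2 of 78 lower and 1 higher (adjusted over the list alone 0; camera adjusted p = 2.08e-08, and adjusted p = 0.588 with an estimated correlation). Digestive enzymes differed gene by gene, with a pancreatic lipase-like gene (LOC118273886) at 43 ± 9.8 CPM against 0.447 ± 0.073 and an aminopeptidase N-like gene (LOC118268349) at 35.2 ± 2.8 against 178 ± 47.

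Of the 2 ryanodine receptor genes, LOC118276673 had 314 ± 90 CPM with cyantraniliprole against 328 ± 56 with tetrazolidamide, a log2 difference of -0.06 (95% interval -0.62 to 0.49, adjusted p = 0.91). LOC118277034 had 100 ± 4.6 CPM against 248 ± 75, a difference of -1.30 (95% interval -1.94 to -0.67, adjusted p = 0.016), with adjusted p = 0.065, 0.055 and 0.063 without tetrazolidamide 3, cyantraniliprole 2 and cyantraniliprole 3. The chloride channel gene LOC118268221 had 0.631 ± 0.36 CPM against 0 (at least 9.72-fold higher, a call that ended without tetrazolidamide 3). The genes LOC118268071, LOC118277861 and LOC118277865 had adjusted p of 0.12, 0.31 and 0.78. Other digestive enzymes were higher (members by edgeR 19 higher and 4 lower of 116, adjusted over the list alone 24 and 6; camera adjusted p = 0.0121, and adjusted p = 0.588 with an estimated correlation), with an adjusted p of up to 0.19 without tetrazolidamide 2 or cyantraniliprole 3. Muscle structural proteins were lower (members by edgeR 0 higher and 2 lower of 39, adjusted over the list alone 0 and 1; camera adjusted p = 0.0284, and adjusted p = 0.582 with an estimated correlation), with an adjusted p of up to 0.24 without tetrazolidamide 3 or cyantraniliprole 3. Chemosensory proteins were lower (members by edgeR 0 higher and 4 lower of 43, adjusted over the list alone 0 and 4; camera adjusted p = 0.0202, and adjusted p = 0.555 with an estimated correlation), with an adjusted p of 0.078 without cyantraniliprole 3. V-type proton ATPase subunits were lower (members by edgeR 0 higher and 2 lower of 22, adjusted over the list alone 0 and 3; camera adjusted p = 0.00386, and adjusted p = 0.602 with an estimated correlation), with an adjusted p of 0.085 without cyantraniliprole 1. The gene count was 985 without tetrazolidamide 1, 803 without tetrazolidamide 3, 943 without cyantraniliprole 2 and 857 without cyantraniliprole 3, and 2975 by DESeq2.

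**Figure D3:**
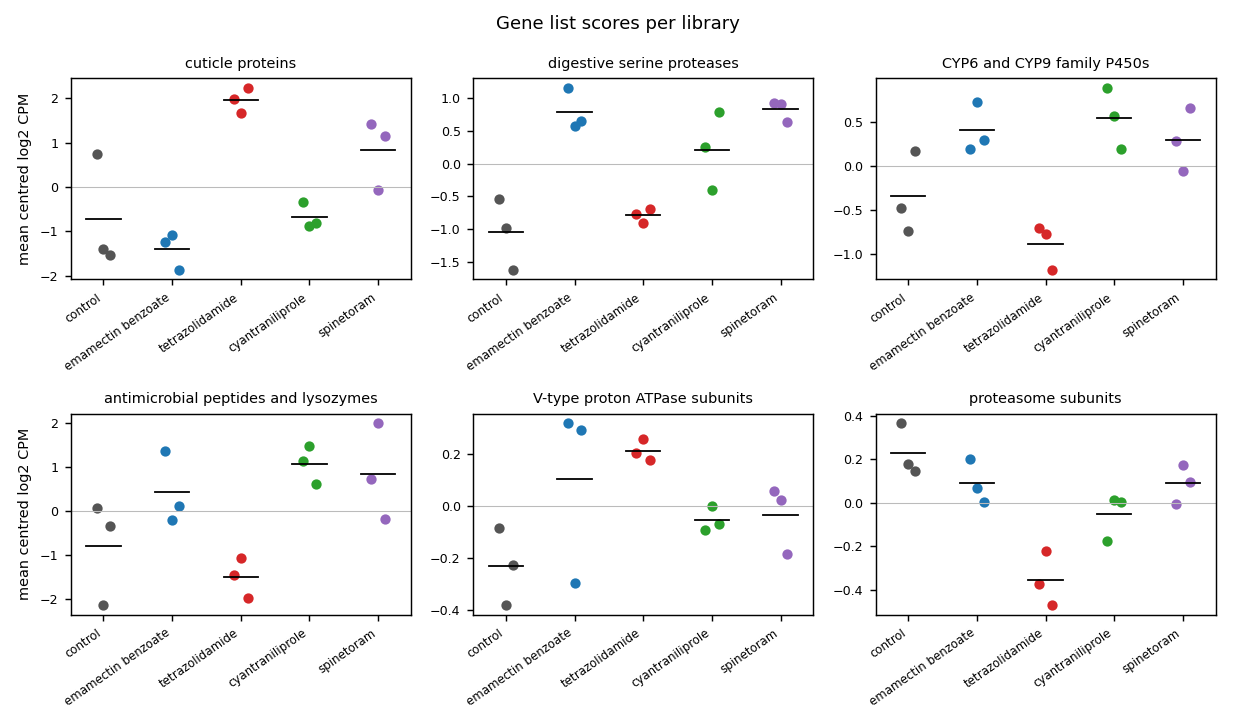
Scores per library (mean centred log2 CPM of the list) for 6 gene lists, with a bar for the mean of 3 libraries. The 3 tetrazolidamide libraries lie above all others for cuticle proteins, and control 1 lies at 0.74 against -1.39 and -1.53 in the other controls.

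The 4 treatments shared many genes, against the same 3 control libraries. The genes given here as examples were chosen after their values were seen. In the same direction in at least 2 treatments were 846 genes, with 98 higher and 9 lower in all 4. Among the 98 were genes already named above, so their rises were not particular to 1 treatment. They include LOC118273155, LOC118273165, LOC118268184, LOC118275193, LOC118277912, LOC118262049, LOC118281769 and LOC118272167. Takeout (LOC118275983), of a family of juvenile hormone binding proteins, had log2 fold changes of 1.55, 2.98, 1.91 and 2.28 with emamectin benzoate, tetrazolidamide, cyantraniliprole and spinetoram. Chitin synthase (LOC118273105) averaged 235, 172, 194 and 207 CPM in those groups against 59.9 in control, and hemicentin-2-like (LOC118274152) 2.1, 0.71, 1.53 and 2.15 against 16.3. Tetrazolidamide and spinetoram shared 333 higher and 104 lower genes, where independence would give 48.8 and 19.8, and cyantraniliprole and spinetoram 161 and 30 against 8.93 and 1.09. The correlation of log2 fold changes across genes was 0.4 to 0.61, and genes are not independent replicates. Simulated unchanged groups, drawn around the means of these same control libraries, gave 0.19 to 0.2. That simulation leaves out the sampling error of the controls. It therefore cannot show how much of the correlation comes from sharing them. Since the controls cannot be divided into 2 sets of 2 or more, a trait of these 3 libraries enters each overlap. The count of 846 was 337 without control 2 and 1411 without control 3. It was 493 and 487 without emamectin benzoate 1 and 3, 525 without tetrazolidamide 1, 557 without cyantraniliprole 3 and 535 without spinetoram 1.

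**Figure D4:**
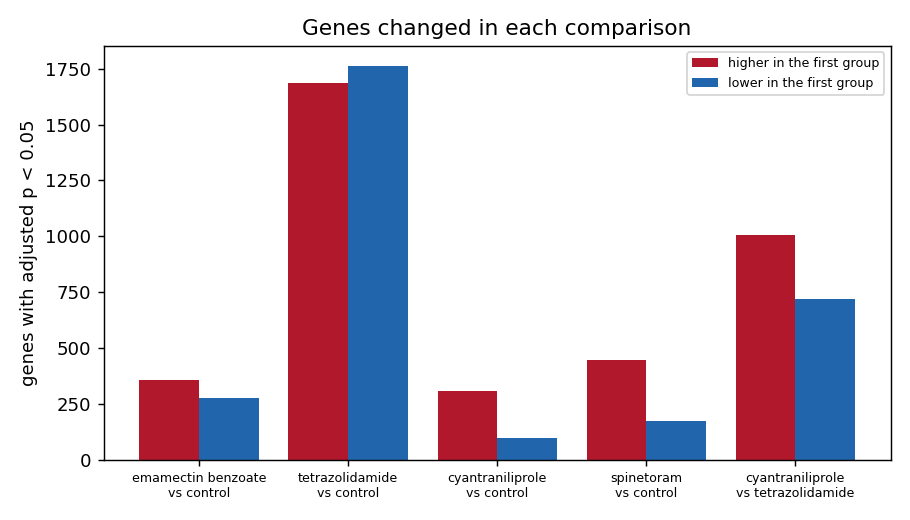
Number of changed genes per comparison (edgeR adjusted p under 0.05), with genes higher and lower in the first-named group as separate bars. Tetrazolidamide against control has 1688 higher and 1764 lower genes, and cyantraniliprole against control 309 and 97.

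Camera called these lists in none of the 5 comparisons: nicotinic acetylcholine receptor subunits, glutamate- and GABA-gated chloride channels, antioxidant enzymes, heat shock proteins, chitin metabolism, fat body storage proteins, silk gland proteins and neuronal markers. Of 15 nicotinic receptor subunits, 2 fell with tetrazolidamide, and of 37 antioxidant enzymes 5, 5, 3 and 4 rose by edgeR and 2, 2, 1 and 0 fell with emamectin benzoate, tetrazolidamide, cyantraniliprole and spinetoram. Of 33 heat shock proteins, 2 fell with emamectin benzoate, 6 rose and 3 fell with tetrazolidamide and 3 rose with spinetoram. Silk gland proteins had a median of -2.7 with tetrazolidamide, where 6 of 12 fell and 1 rose. Of 18 fat body storage proteins, 2 rose and 4 fell with tetrazolidamide. Chitin metabolism had 2 of 22 members higher and 2 lower with tetrazolidamide and 2 higher with spinetoram, and neuronal markers had 3 of 31 higher and 2 lower with tetrazolidamide.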

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

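All tests of explanations and of other splits given here were chosen after the results were seen. Differences of effect between 2 treatments, each tested directly as cyantraniliprole against tetrazolidamide, were singled out where that test passed and the medians against control had opposite signs. None of the lists below was called for tetrazolidamide against control, so the sign of its median there is not established. Immune recognition and melanization was not called for cyantraniliprole against control either. Antimicrobial peptides and lysozymes had a median log2 difference of 2.58 between the treatments (medians against control 1.26 with cyantraniliprole and -0.86 with tetrazolidamide, camera adjusted p = 9.44e-05, and adjusted p = 0.582 with an estimated correlation). CYP6 and CYP9 family P450s had 0.62 (0.89 and -0.14, adjusted p = 0.000321, and adjusted p = 0.555 with an estimated correlation). Immune recognition and melanization had 0.33 (0.2 and -0.27, adjusted p = 0.00572, and adjusted p = 0.555 with an estimated correlation). Muscle structural proteins had -0.3 (-0.34 and 0.15, adjusted p = 0.0284, and adjusted p = 0.582 with an estimated correlation). That call ended without tetrazolidamide 3 or cyantraniliprole 3, where the adjusted p reached 0.24. Oxidative phosphorylation had -0.43 (-0.4 and 0.03, adjusted p = 2.08e-08, and adjusted p = 0.588 with an estimated correlation).

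With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count (1 of 10 splits) in each comparison, with 634, 3452, 406, 622 and 1724 genes for emamectin benzoate, tetrazolidamide, cyantraniliprole and spinetoram against control and cyantraniliprole against tetrazolidamide, where the highest of the other splits gave 1, 1, 8, 30 and 1. Over 50 splits of the 15 libraries, 1 gave as many genes with any difference as the real 3437, the real one itself, and the highest other gave 295. This argues, at that share, against a random assignment of the 15 libraries to groups. Tetrazolidamide alone called 3452 genes, so it says nothing on emamectin benzoate, cyantraniliprole or spinetoram by themselves. Nor can it tell a treatment from a difference between cohorts, on which the labels are silent. The overlap of 846 genes was reached by 1 of 50 splits, the highest other being 1. Most other splits called no gene in the test of any difference, which leaves little to overlap. They also broke up the control group, so they cannot show whether treatments share genes. The 74 list calls were reached by 1 of 50 splits, but every other split also gave calls, from 29 to 66. The preset-correlation test thus called many lists in groupings without meaning.

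The 36 genes at 0 in tetrazolidamide alone were set against chance, depth, the genome and copies. Of the 455 sets of 3 libraries 1 held as many, the real one, and the highest other held 5, and counting error alone would put an expected number of 0.0523 genes at 0 there, over the 12742 genes above 0 in the other 12 libraries (the 36 would expect 8.84 to 552 read pairs), which argues against chance and against too few reads in the tetrazolidamide libraries. Of the 36, 23 lay within 500 kb of another, against a median of 6 and a highest value of 18 in 10000 draws from 1728 other fallen genes (share 0.0001, the smallest they can give). Stretches of the genome that differ between the tetrazolidamide animals and the reference are thus a candidate explanation. Rows of neighbouring genes low by fold alone also occurred with emamectin benzoate, cyantraniliprole and spinetoram. Of their row genes 5 of 72, 1 of 37 and 0 of 19 were called by edgeR, against 96 of 140 with tetrazolidamide. Reads of a near-identical copy assigned to the other copy stay open: 27 of the genes shared a description with others, and of the 12 that made up 20% or more of the summed control level, 6 kept a sum of 80% of control or more, which decides nothing without reads. A regulated loss of expression was not tested.

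Cuticle genes higher with tetrazolidamide were set against 3 explanations. A few abundant genes taking more of the counts is argued against, since the 20 most abundant genes held 27.8% of units against 27.3%, a shift of at most 0.01 on the log2 scale against a lower quartile of 0.58 for the list. Control libraries low in cuticle transcripts is argued against as the whole cause, since 63 members were lower with cyantraniliprole than with tetrazolidamide. Animals at another phase of the moult may account for part of it, and this stays open. The leading axis of cuticle variation within other groups (44.8% of variance) had an absolute correlation across genes of 0.29 with the effect (Spearman 0.12), and genes are not independent replicates.

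Camera called digestive serine proteases, other digestive enzymes and CYP6 and CYP9 genes higher with emamectin benzoate, cyantraniliprole and spinetoram at the preset correlation, with adjusted p of 0.274 to 0.568 under an estimated one, and 10, 4 and 11 of 101 proteases, 14, 8 and 14 of 116 other enzymes and 6, 2 and 4 of 50 CYP6 and CYP9 genes rose (1 protease and 6 other enzymes fell with emamectin benzoate). As a cause of the protease result, 1 control library with little midgut RNA is argued against for emamectin benzoate and spinetoram. Proteases held 0.625% to 0.937% of units over the controls, against 2.359% to 3.325% and 1.762% to 2.678%. With cyantraniliprole they held 0.793% to 2.081%, which overlaps the controls. Without each control 9 of 9 protease calls were kept, but at the preset correlation, which also called many lists in other splits. Control 1 and control 2 both had low peritrophic matrix scores, so leaving out 1 control does not test little midgut RNA in both. A larger midgut share of the RNA stays open as a cause of the protease result. With the peritrophic matrix score as a covariate 3 of 3 calls were kept with a mean difference over 2 SE in log2(FPKM + 1). The differences were 1.42, 0.91 and 1.28 (SE 0.25, 0.28 and 0.26), against 1.38, 0.85 and 1.23 (SE 0.2 each) without it. The score thus did not follow the proteases within groups and cannot take out a midgut share. With tetrazolidamide 4 of 4 abundant peritrophic genes (mean of at least 100 CPM) were higher but 13 of 26 abundant proteases. With emamectin benzoate, cyantraniliprole and spinetoram, 138 of 156 fold changes of abundant digestive and peritrophic genes were higher. Each gene counts once per treatment there, against the same 3 controls, so these are not separate observations. Called higher by edgeR were 5, 2 and 3 of 26 proteases, 4, 2 and 3 of 22 other enzymes and 0, 1 and 1 of 4 peritrophic genes, with 0 called lower. For CYP6 and CYP9 genes 3 of 3 calls were kept and the differences were 0.39, 0.52 and 0.27 (SE 0.22, 0.24 and 0.22) against 0.47, 0.62 and 0.35 (SE 0.18 each), but 1 of 3 lay over 2 SE, a bar set after these values were seen, so a larger midgut share of the RNA stays open. It also stays open for other digestive enzymes, where 2 of 3 calls were kept, 1 of them with a difference over 2 SE, and that of emamectin benzoate ended (adjusted p = 0.0772, difference 0.45, SE 0.21, to 0.11, SE 0.17), and a response of midgut cells was not separated from a change in their share.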

How the results depend on the processing

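Alternatives that use DESeq2 on only the groups compared, limma-trend without weights, counts per read pair, a covariate, the genes without those at 0 in 1 group alone, list tests on log2 CPM, without stray members or without 1 library, and all of the overlap were chosen after the data were seen, and the others before. DESeq2 called 1783, 1532, 1880 and 2975 genes for emamectin benzoate, cyantraniliprole and spinetoram against control and cyantraniliprole against tetrazolidamide, 6114 for any group and an overlap of 2420, against 634, 406, 622, 1724, 3437 and 846 by edgeR. On data simulated for tetrazolidamide in steps of 1 read pair DESeq2 made 74 false calls and edgeR 1, and without such steps edgeR made 8. These data were drawn from the dispersions of edgeR with the same spread in every group. They therefore cannot show the false calls of either tool against the real controls, nor explain the larger DESeq2 counts. With only the libraries of the groups compared, edgeR called 0 genes for emamectin benzoate (2574 at an unadjusted p under 0.05), 1583 for tetrazolidamide, 0 for cyantraniliprole (2343) and 2 for spinetoram. It called 1304 for cyantraniliprole against tetrazolidamide, a fit without controls. DESeq2 called 1503, 3533, 1005 and 998, and 2961 for cyantraniliprole against tetrazolidamide. Fewer libraries give a less certain estimate of the spread, but the controls also varied more than most groups. Pairs of controls had Spearman correlations of 0.907 to 0.936, against 0.932 to 0.972 for pairs within treated groups. A spread shared by all libraries may thus be too small for comparisons with control. Fewer libraries alone did not remove the calls between cyantraniliprole and tetrazolidamide, where the fit of all libraries gave 1724. Nor did the controls remove those of tetrazolidamide. Whether the fewer libraries or the spread of the controls lowered the other counts was not tested. Limma with array weights called 954, 959 and 3198 for cyantraniliprole, spinetoram and cyantraniliprole against tetrazolidamide, 5684 for any group and an overlap of 1336, and the same fit without weights 607, 710, 1894, 3504 and 977. For tetrazolidamide the stricter filter, which tested 6663 genes, gave 2276, and an absolute log2 fold change of at least 1 gave 2293.

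Leaving out 1 library gave 45 to 750 genes for emamectin benzoate (lowest without emamectin benzoate 3, highest without control 3), 78 to 1214 for cyantraniliprole and 35 to 1118 for spinetoram (both lowest without control 2, highest without control 3). It gave 2397 to 3413 for tetrazolidamide, 803 to 1237 for cyantraniliprole against tetrazolidamide (lowest without tetrazolidamide 3), 2134 to 4088 for any group (lowest without tetrazolidamide 1) and an overlap of 337 to 1411 (without control 2 and control 3). The cause was not tested. The list tests gave 0 calls with an estimated correlation, 55 with the peritrophic matrix covariate and 64 to 87 without 1 library, against 74. Cytosolic ribosomal proteins with spinetoram had a mean difference in log2(FPKM + 1) of 0.099, from 0.03 without spinetoram 2, where camera ranked them lower than other genes (adjusted p = 0.509), to 0.17 without spinetoram 3.

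A replicate block gave 364, 3106, 284, 447 and 1379 genes, 2631 for any group, and 78 list calls. Of 30 pairs of libraries with the same number, 4 had correlated deviations over 0.1 (-0.154 to 0.373), and 5 of 15 libraries correlated best with their own number, so the numbers were not taken to pair samples. The highest values were 0.373, 0.26 and 0.18, all among replicate 1 of control, emamectin benzoate and cyantraniliprole. Replicate 1 of tetrazolidamide had -0.154, -0.108, -0.077 and -0.095 with those of the other groups. Something shared by some replicate 1 libraries was not tested. Of 234 passing results for named genes, 70 kept their call in every setting run and 0 reversed. These were uneven. With only the libraries of the groups compared, edgeR kept 0 of 38 for emamectin benzoate, 0 of 45 for cyantraniliprole and 2 of 44 for spinetoram. It kept 42 of 54 for tetrazolidamide and 47 of 53 for cyantraniliprole against tetrazolidamide. Without each library in turn 8, 10, 5, 44 and 30 were kept.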

Other observations

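The test of neighbouring genes was chosen after the results were seen, and the other values here come from planned lists. Ecdysteroid and juvenile hormone genes had 2 of 43 members higher and 13 lower with tetrazolidamide (median -0.69, camera adjusted p = 0.0503). Juvenile hormone esterase-like (LOC118275676), of the family that degrades juvenile hormone, fell to 0.242 ± 0.1 CPM from 3.48 ± 2 (SD, n = 3, edgeR adjusted p = 0.0095). Neverland (LOC118281031), an early enzyme of ecdysteroid synthesis, had 2.56 ± 0.3 CPM with cyantraniliprole against 0 with tetrazolidamide, at least 40.1-fold higher. It lies in the stretch of 20 neighbouring genes that was low in tetrazolidamide, and is 1 of the genes at 0 for which that stretch was chosen.

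Rows of at least 4 neighbouring tested genes lower by more than 3 on the log2 scale were also counted in each comparison. Tetrazolidamide had 21 such rows with 140 genes, of which 96 were called lower. Its longest row had 15 genes, where 200 shuffles of gene order gave at most 6. Emamectin benzoate had 12 rows with 72 genes, of which 5 genes were called lower, cyantraniliprole 6 with 37 (1 called) and spinetoram 4 with 19 (0 called by edgeR, with 3324 genes at an unadjusted p under 0.05 in that comparison and 1880 by DESeq2). The longest had 14, 9 and 7 genes, where the shuffles gave at most 4 for each. The row of 14 with emamectin benzoate lay within the row of 15 with tetrazolidamide, so rows defined by fold alone were not particular to tetrazolidamide. Few row genes were called with emamectin benzoate, cyantraniliprole or spinetoram, so their rows carry less weight. Shuffling gene order also parts neighbouring copies of a family, so it does not account for them. Cyantraniliprole against tetrazolidamide, where tetrazolidamide was the higher group, had 11 rows with 78 genes (57 called), the longest of 10 against at most 4 in the shuffles. The difference in number between treatments was not tested.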
